A study of Mus musculus with 12 samples.

How the data were processed

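The deposited table holds CPM per gene symbol and library, which the authors made from read counts, per the labels with TopHat2 2.1.0, HTSeq and edgeR, on genome builds named as mm10 and GRCm38. Versions of HTSeq and edgeR, the annotation behind the symbols, the strand setting of the counting, the name and dose of the inhibitor and the number of KO clones are not given in the sources used here. The submitters' processing notes were the only source for these steps. The CPM were scaled per library over all counted alignments, including 5 HTSeq summary lines that are not genes. In each library 100% of the values above 0 were whole reads within 0.02 reads once multiplied out, so read counts were recovered for the count-based tests. Of all counted alignments 58.95 to 64.06% fell in genes, 28.59 to 34.92% had no unique position, 4.997 to 6.374% fell outside annotated features and 0.9944 to 1.129% were ambiguous.

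The table had 12 columns that matched the sample labels and 4 further per-sample columns that matched none and were not used here. It held 24421 symbols, of which 23350 were found in GENCODE M21, which gave the positions; 10509 of the 10899 tested genes were matched. Among the symbols 27 had been turned into dates by a spreadsheet, 15 of them in genes that were tested; they stayed in the tests and are not named. No mitochondrial-encoded gene was in the table. Replicate libraries had a Pearson r of 0.9952 to 0.997 on the log2 scale, and their differences exceeded sampling of reads, with a chi-square per degree of freedom of 15.36 to 31.38.

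CPM were rescaled to the gene reads of each library, so that the 5 summary lines did not enter the library sizes. The design written before the data were examined named the deposited scaling, and the gene-read scaling replaced it afterwards; the deposited scaling was kept as an added alternative. Genes with at least 1 CPM in at least 2 libraries were tested. The test was limma 3.58.1 in R 4.3.3 with a trend on log2(CPM + 1), in a single fit with 6 group means over all 12 libraries (residual degrees of freedom 6, prior degrees of freedom 3.54). Genes with a Benjamini-Hochberg adjusted p under 0.05 over the tested genes of a comparison were called. Of the comparisons 9 were fixed before the data were examined, as were the alternatives except those named as added here; a comparison of the KO response with the Jak-inhibited response to LPS was added afterwards. For genes of described lists the p were also adjusted over the list alone. Lists with at least 5 measured members were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists tested, and again with an estimated correlation. Of 22 lists 19 were tested; the lymphocyte, the stromal, epithelial and endothelial, and the mitochondrial-encoded lists had fewer than 5 measured members. Where a group had 0 reads the fold was given as a lower bound from a floor of 3 reads over the group, and no bound was given for Tbx3.

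Genes were named by a rule. For each comparison these were the 6 largest changes in each direction among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, or for interactions differences of the same sign in every replicate. To these came 2 to 4 members of each described list with the largest changes, and 17 genes followed in every comparison, of which a gene is not reported here and the others were Parp14, Parp9, Dtx3l, Ifnb1, Tnf, Il6, Il1b, Nos2, Cxcl10, Ifit1, Irf7, Socs1, Socs3, Cish, Mx1 and Rsad2. Predicted genes were counted and not named, and of the genes that met the rule not all are named in the text. Cd74 and the interaction of Tbx3 were added outside the rule after values had been seen.

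The labels name no separate cultures, so the p-values measure only the spread between these samples, which may be technical. The labels number the libraries as replicate 1 and 2 in each group. Across genes, the difference of replicate 1 minus 2 correlated between groups in all 15 pairs of groups (0.468 to 0.737, median 0.622), so the numbers behaved like a pairing. Calls and p-values are of the fit without a block unless the block is named. In that fit the difference between replicate numbers counts as spread, so changes can be missed. A fit with the replicate number as a block was run beside it. The labels name no shared day or batch, and these correlations were first printed in the same run as the counts of the blocked fit.

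Alternatives were a pseudocount of 0.25, no filter, a filter of 5 CPM, rescaling by the median of ratios over genes with at least 5 CPM in all libraries, the replicate block, only the groups compared, a limit of 2-fold, each library of a comparison left out in turn, and the count-based tests of edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Added afterwards were the deposited scaling and, for the lists other than the type I interferon list, all alternative settings. In untreated KO and WT cells limma called 1055 genes, edgeR 1009 and DESeq2 1234; after LPS they called 1510, 1511 and 1682. In WT cells after LPS limma called 7332, edgeR 6474 and DESeq2 6543.

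The pipeline was tried on a simulated set of 10722 genes, built from the mean level of each gene over all 12 libraries. In its KO libraries with LPS 200 genes were changed by a known fold. Between KO and WT cells after LPS, 68% of the genes changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold or 8-fold were found. Of the calls 5.67% were false. In the same set the inhibitor alone against untreated cells, where no gene was changed, gave 0 calls. A list moved as a whole was called (adjusted p = 3.46e-20), and 0 of 19 lists left unmoved were called. Genes and libraries were drawn independently, so these rates do not cover paired replicates or correlated list genes. The overlap of 2 comparisons with libraries in common was set against 100 sets simulated with no true change, taking as many genes with the lowest t as had been called lower, with and without the replicate block, and standard errors of medians came from 2000 bootstrap draws over genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.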

Results

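The data were RNA sequencing of the mouse macrophage line RAW264.7, in wild-type (WT) cells and in knockout (KO) cells for Parp14, the gene of an ADP-ribosyltransferase. Cells were left untreated or were treated for 2 h with lipopolysaccharide (LPS), a bacterial cell wall component sensed by the receptor TLR4, with an inhibitor of Jak kinases, or with both. The 12 libraries formed 6 groups of 2: untreated WT, WT with LPS, WT with the inhibitor, WT with both, untreated KO and KO with LPS. Single libraries are named by group and replicate, such as WT_UT replicate 1 for untreated or WT_LPS_JAKi replicate 2 for LPS with the inhibitor. In the libraries analysed here the inhibitor was given to WT cells alone, and its name is not given in the sources used here. Reads counted in genes ranged from 35.9 to 45.7 M per library, out of 57.1 to 74.2 M counted in all. The table held 24421 gene symbols, of which 10899 passed the minimum level for testing. Levels are in CPM over the gene reads of a library, as mean ± SD of n = 2 libraries per group. Changes are differences of log2(CPM + 1) with their standard error (SE) and the adjusted p of limma. The first 2 principal components held 84.4% and 8.92% of the variance: all libraries with LPS lay on the same side of the first, and all KO libraries on the same side of the second. On this scale the change of a gene near or under 1 CPM is smaller than the ratio of its levels. Positions are on genome build GRCm38 with the GENCODE M21 annotation.

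Parp14 (chromosome 16, 35832874 to 35871544, minus strand) was measured first, as the gene that was knocked out. Its level was 88.1 ± 16.5 CPM in untreated WT cells and 11.0 ± 1.39 CPM in untreated KO cells (SD, n = 2), or 12.5% of the WT level. After LPS it was 367 ± 73.8 CPM in WT cells and 37.7 ± 3.96 CPM in KO cells, or 10.3% of the WT level. The KO value was lower in both conditions, by a log2 change of -2.89 (SE 0.2, adjusted p = 2.66e-05) untreated and -3.24 (SE 0.2, adjusted p = 1.12e-05) after LPS. LPS raised the remaining Parp14 reads in KO cells by 1.69 (SE 0.2, adjusted p = 4.52e-05), against 2.04 (SE 0.2, adjusted p = 1.24e-05) in WT cells. In WT cells with LPS and the inhibitor the level was 124 ± 19.7 CPM, lower than with LPS alone by a log2 change of -1.56 (SE 0.2, adjusted p = 0.00403).

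**Figure D1:**
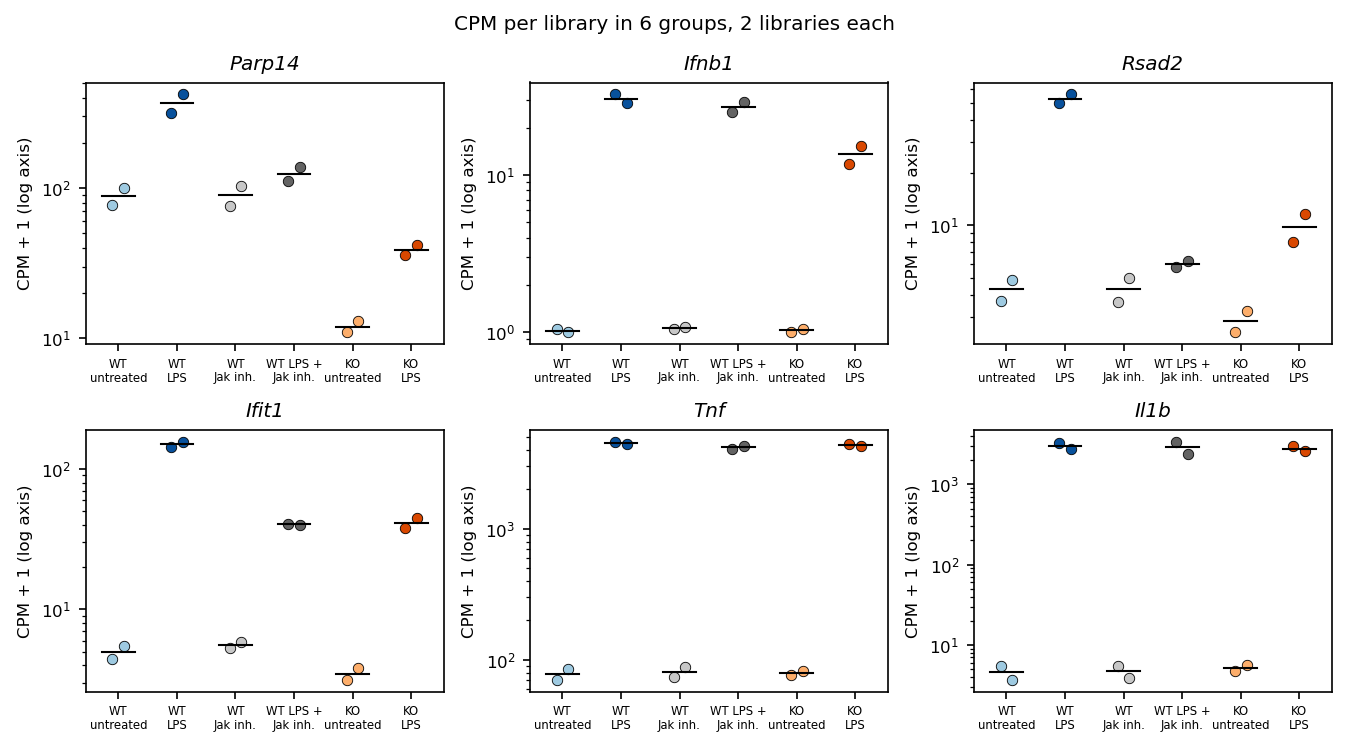
Levels of Parp14, Ifnb1, Rsad2, Ifit1, Tnf and Il1b in the 6 groups, as CPM + 1 on a logarithmic axis. Each point is a library (2 per group) and each bar is the group mean; Rsad2 stood at 51.7 CPM in WT cells after LPS, 8.81 in KO cells after LPS and 5.04 in WT cells with LPS and the inhibitor, while Tnf stood at 4517, 4354 and 4181 CPM.

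The first comparison asked what 2 h of LPS did to WT cells. Genes of inflammatory mediators rose most: Il1b (interleukin-1 beta; chromosome 2, 129364570 to 129371139, minus strand) went from 3.53 ± 1.21 to 3017 ± 377 CPM, a log2 change of 9.40 (SE 0.23, adjusted p = 2.12e-09). The neutrophil chemokine Cxcl2 (chromosome 5, 90903871 to 90905938, plus strand) rose by 8.85 (SE 0.058, adjusted p = 1.89e-13) and the cytokine Lif (chromosome 11, 4257557 to 4272514, plus strand) by 8.68 (SE 0.0897, adjusted p = 4.83e-12). Irg1, the itaconate-forming enzyme, Il1a and the chemokine Ccl22 followed with 7.75, 7.68 and 7.15. Tnf rose from 76.9 ± 10.5 to 4517 ± 130 CPM. Ifnb1, the gene of interferon beta (chromosome 4, 88522025 to 88522774, minus strand), had 2 reads over both untreated libraries and stood at 29.7 ± 2.79 CPM after LPS. Among the genes that fell, Kbtbd11 went from 253 ± 23.2 to 8.97 ± 0.512 CPM, a log2 change of -4.67 (SE 0.106, adjusted p = 1.46e-09). The transcription factors Bhlhe41 and Klf4 fell by 4.19 and 3.80 on the log2 scale, and the sphingosine-1-phosphate receptor S1pr1 fell by 3.87.

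The interferon and inflammatory lists moved up as groups. Type I interferon-stimulated genes were measured for 59 symbols, of which 44 were higher and 4 lower, with the same counts adjusted over the list alone and a median log2 change of 0.86 (camera adjusted p = 2.22e-21). That call was lost at an adjusted p = 0.179 with an estimated correlation. Ifit1 (chromosome 19, 34640871 to 34650009, plus strand) rose from 3.97 ± 0.778 to 149 ± 8.57 CPM, Isg15 by 4.88 (SE 0.248) and the RNA sensor Ifih1 by 3.92 (SE 0.0702) on the log2 scale. Of the 8 interferon-inducible GTPases 7 were higher and 0 lower, or 8 and 0 adjusted over the list alone, with Gbp5 at 3.05 (SE 0.113); the list median was 1.70 (camera adjusted p = 1.38e-08, adjusted p = 0.0683 with an estimated correlation). All 35 NF-kB targets were higher, as they were adjusted over the list alone, with a median of 3.19 (camera adjusted p = 9.07e-40). Nfkbiz, an NF-kB cofactor, rose by 6.55 (SE 0.0989) and Ptgs2, the inducible cyclooxygenase, by 6.25 (SE 0.256). Of the 30 cytokines and chemokines 29 were higher and 0 lower, also adjusted over the list alone, with a median of 4.29 (camera adjusted p = 1.54e-33). Immediate early genes were 17 higher and 4 lower of 21, the same adjusted over the list alone, with Myc at 5.15 and Dusp1 at 4.34 (camera adjusted p = 3.63e-10, adjusted p = 0.0683 with an estimated correlation).

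Components of the receptors moved in both directions. Of the 27 TLR4 signalling genes 11 were higher and 9 lower, the same adjusted over the list alone, and 17 and 6 after rescaling by the median of ratios (median 0.08, camera adjusted p = 0.000541): the ubiquitin ligase Peli1 rose by 3.66 (SE 0.0661), while Tlr4 itself fell by 2.44 (SE 0.258, adjusted p = 2.08e-05) on the log2 scale. In the Jak-STAT list of 26 genes 9 were higher and 14 lower, the same adjusted over the list alone, and 12 and 9 after rescaling. Its feedback members Pim1 and Socs3 rose by 5.15 and 4.70, and Cish, at 0 reads untreated, was at least 528-fold higher (floor of 3 reads over the group). This list had a negative median, -0.21, a positive mean, 0.46, and an upward test (camera adjusted p = 0.0475, adjusted p = 0.37 with an estimated correlation; adjusted p = 0.107 after rescaling by the median of ratios). Of 18 MHC class I presentation genes 5 were higher and 5 lower, the same adjusted over the list alone, and 11 and 1 after rescaling. Their median was 0.08, their mean -0.004 and the test upward (camera adjusted p = 0.0165, adjusted p = 0.154 with an estimated correlation).

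The cell cycle list fell: 31 of 32 genes were lower, 32 adjusted over the list alone and 22 after rescaling, with a median of -0.68 (camera adjusted p = 3.4e-05, adjusted p = 0.27 with an estimated correlation). The replication licensing factor Cdc6 went from 52.0 ± 4.88 to 12.2 ± 0.109 CPM, and the mitotic genes Cenpf and Plk1 changed by -1.44 (SE 0.101) and -1.27. Of 24 sterol synthesis genes 10 were higher and 9 lower, the same adjusted over the list alone, and 15 and 5 after rescaling, with Dhcr7 at -1.61 and Idi1 at 1.05 (median 0.06, camera adjusted p = 0.0103, adjusted p = 0.0683 with an estimated correlation). Osteoclast markers (4 higher and 1 lower of 8, or 6 and 0 after rescaling; camera adjusted p = 0.00358, adjusted p = 0.27 with an estimated correlation) included Mmp9, a secreted gelatinase, at 2.84. The dendritic cell and MHC class II list (5 higher and 0 lower of 9; camera adjusted p = 0.000512, adjusted p = 0.154 with an estimated correlation) included the activation marker Cd83 at 4.07. For both lists the counts were the same adjusted over the list alone.

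The other 7 lists were not called. The PARP family and ADP-ribose list had 2 higher and 10 lower of 17 (adjusted p = 0.985), with Tiparp at 1.42. The LXR and lipid handling list had 2 higher and 8 lower of 16 (adjusted p = 0.835), with the cholesterol exporters Abca1 at 2.61 and Abcg1 at -2.94. Glycolysis and hypoxia genes were 7 higher and 6 lower of 23 (adjusted p = 0.0592), and NRF2 oxidative stress genes 4 and 6 of 16 (adjusted p = 0.0525), with the cystine transporter Slc7a11 at 3.25. With the replicate block the NRF2 list was called (camera adjusted p = 0.042). Unfolded protein and integrated stress response genes were 5 higher and 9 lower of 20 (adjusted p = 0.26), and heat shock genes 1 and 3 of 11 (adjusted p = 0.322). Macrophage identity genes were 2 higher and 7 lower of 26, or 2 and 6 adjusted over the list alone, with the Fc receptor gene Fcgr1 at -1.89 (adjusted p = 0.553). For the others of these 7 lists the counts were the same adjusted over the list alone. After rescaling the counts higher and lower were 4 and 5 for the PARP list, 6 and 5 for LXR, 8 and 4 for glycolysis, 7 and 2 for NRF2, 6 and 6 for unfolded protein, 6 and 1 for heat shock and 4 and 5 for macrophage genes. Camera compares a list with the other genes, so the tests of the LXR, glycolysis, NRF2, unfolded protein, macrophage and heat shock lists were upward with medians of -0.28, -0.15, -0.02, -0.32, -0.18 and -0.04.

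In all, 1493 genes were higher and 5839 lower, of which 516 and 1217 changed at least 2-fold. The 516 genes took 2.39% of gene reads in untreated WT cells and 12.4% after LPS, which lowers the share of the other genes by 0.156 on the log2 scale, while the median of all genes shifted by -0.302. After rescaling by the median of ratios that shift was -0.0398, and 2873 genes were higher and 3537 lower. By edgeR 3052 were higher and 3422 lower and by DESeq2 3318 and 3225, so the split between rising and falling genes rests on the scaling. Changes under about that shift are therefore read relative to the other genes.

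The same comparison in KO cells asked what LPS did in the knockout line. Il1b rose by 9.09 (SE 0.23, adjusted p = 2.64e-09), Lif by 8.95 (SE 0.0897, adjusted p = 3.61e-12) and Cxcl2 by 8.68 (SE 0.058, adjusted p = 2.26e-13), followed by Csf3, the granulocyte growth factor (8.04), Irg1 (7.80) and Il1a (7.39). Tnf reached 4354 ± 87.9 CPM from 78.6 ± 4.48 CPM. Ifnb1 went from 2 reads over both untreated libraries to 12.6 ± 2.62 CPM. Kbtbd11 fell by 4.85, the prostaglandin-degrading enzyme Hpgd by 4.07 and the sialyltransferase St8sia4 by 3.89 on the log2 scale. Among the 59 interferon-stimulated genes 22 were higher and 12 lower, the same adjusted over the list alone, and 34 and 4 after rescaling. The list median was 0.33 (camera adjusted p = 1.68e-07, adjusted p = 0.402 with an estimated correlation), and ranged from 0.158 without KO_UT replicate 1 to 0.435 without KO_LPS replicate 1. Isg15 rose by 4.25 (SE 0.248), Ifit1 by 3.58 (SE 0.132) and Rsad2, the antiviral enzyme viperin (chromosome 12, 26442746 to 26456452, minus strand), by 1.78 (SE 0.221). Of the 8 GTPases 5 were higher and 0 lower, the same adjusted over the list alone (median 0.73, camera adjusted p = 0.000339, adjusted p = 0.247 with an estimated correlation). All 35 NF-kB targets were higher, also adjusted over the list alone (median 3.33, camera adjusted p = 5.12e-39), as were 28 of 30 cytokines and chemokines, with the same 28 adjusted over the list alone (median 3.06, camera adjusted p = 1.63e-30). The cell cycle list had 0 higher and 30 lower of 32, also adjusted over the list alone, and 24 lower after rescaling (camera adjusted p = 2.88e-05, adjusted p = 0.289 with an estimated correlation).

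Among the other lists, 5 more were called in KO cells, and all of these calls were lost with an estimated correlation: immediate early genes (adjusted p = 1.97e-10, and adjusted p = 0.0909 with an estimated correlation), TLR4 signalling (0.00139 and 0.0529), glycolysis and hypoxia (0.0486 and 0.611), osteoclast markers (0.00644 and 0.337) and the dendritic cell and MHC class II list (0.000221 and 0.177). The glycolysis list had a negative median, -0.15, a mean of 0 and an upward test. In all, 1518 genes were higher and 5748 lower, of which 523 and 1237 changed at least 2-fold; after rescaling the counts were 2911 and 3608, and the median of all genes moved from -0.29 to -0.0343. Across the 10899 genes the LPS response of KO cells had a Pearson r of 0.97 (Spearman rho 0.957) with that of WT cells, where genes are not independent replicates. Of the 1733 genes changed at least 2-fold in WT cells 1495 changed at least 2-fold the same way in KO cells, and 7 genes were called in opposite directions.

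Without treatment, KO and WT cells were compared to see what differed between the lines before LPS. Hpgd (chromosome 8, 56294585 to 56321043, plus strand) was at 1.54 ± 0.87 CPM in WT and 160 ± 58.2 CPM in KO cells, a log2 change of 5.98 (SE 0.393, adjusted p = 1.95e-05). The transcription factor Tbx3 (chromosome 5, 119670669 to 119684724, plus strand) had 0 reads in all WT groups and 55.2 ± 7.25 CPM in untreated KO cells (adjusted p = 3.15e-09). The basement membrane gene Nid2, Dmwd, the monocyte chemokine receptor Ccr2 and the protease inhibitor Slpi were higher in KO cells by 3.87, 3.47, 3.23 and 3.11. Besides Parp14, Ndrg4 was lower by a log2 change of -3.30 (SE 0.146, adjusted p = 1.55e-06) and the glycoprotein gene Gpnmb (chromosome 6, 49036546 to 49070929, plus strand) by -2.99 (SE 0.239, adjusted p = 5.94e-05), followed by Plod2 (-2.26), Slc6a8 (-2.15) and Cd28 (-1.96). Of the 17 genes followed throughout, Parp14, Parp9 and Ifit1 were lower and 14 were not called.

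Genes of sterol synthesis were lower together in untreated KO cells: 19 of 24 measured members, or 21 adjusted over the list alone, with 0 higher and a median log2 change of -0.38 (camera adjusted p = 2.13e-15, adjusted p = 0.00176 with an estimated correlation). Hmgcs1, which makes HMG-CoA, was at 139 ± 4.82 CPM in WT and 82.8 ± 4.55 CPM in KO cells, and Nsdhl, an enzyme after lanosterol, changed by -0.66. The unfolded protein and integrated stress response list was higher: 9 of 20 genes, or 12 adjusted over the list alone, with 0 lower and a median of 0.42 (camera adjusted p = 2.01e-11, adjusted p = 0.00622 with an estimated correlation). Its largest called changes were in Trib3, a target of ATF4 (1.19, SE 0.186), and the chaperone genes Pdia4 (0.75, SE 0.0946) and Sdf2l1 (0.70, SE 0.0924). Interferon-stimulated genes were lower for 7 of 59 members and higher for 0, or 8 and 0 adjusted over the list alone and 2 and 0 after rescaling; with the replicate block 34 were lower and 2 higher. Their median was -0.23 (camera adjusted p = 2.3e-06, adjusted p = 0.826 with an estimated correlation), with Ifih1 at -0.47 (SE 0.0702) and Ifit1 at -0.51 (SE 0.132). The median ranged from -0.362 without WT_UT replicate 1 to -0.159 without WT_UT replicate 2. Rescaling ended the call of Ifit1 (adjusted p = 0.0543) and of Parp9 (adjusted p = 0.0513).

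Marker lists of other cell states were mixed. In the macrophage identity list 4 genes were higher and 6 lower of 26, or 5 and 8 adjusted over the list alone, with the transcription factor Maf at 2.43 and the lysozyme gene Lyz1 at 1.37 (median -0.12, mean 0.08, downward test with adjusted p = 0.6). Among osteoclast markers, 1 was higher and 2 lower of 8, or 1 and 3 adjusted over the list alone: Mmp9 at 2.13, the proton pump subunit Atp6v0d2 at -1.59 and the acid phosphatase Acp5 at -0.87 (adjusted p = 0.405). In the dendritic cell and MHC class II list 4 genes were higher and 1 lower of 9, also adjusted over the list alone (adjusted p = 0.219). The MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 stood between 0.126 and 0.265 CPM in untreated WT cells and at 5.58 ± 1.72, 4.68 ± 1.11 and 4.77 ± 1.09 CPM in untreated KO cells. Cd74, the invariant chain that pairs with class II molecules, was at 135 ± 0.587 and 137 ± 0.805 CPM, and Cd83 was lower in KO cells (-1.25, SE 0.255, adjusted p = 0.0137). The cell cycle and heat shock lists had 0 members higher or lower by limma, also adjusted over the list alone; with the replicate block 1 cell cycle gene was higher. In all, 470 genes were higher and 585 lower in untreated KO cells, and 2685 in all with the replicate number as a block. Under the deposited scaling 324 were higher and 1026 lower, so the split depends on the scaling. Leaving out any of the 4 libraries lowered the count of 1055 to between 477 and 548.

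After LPS, KO and WT cells were compared to see whether the interferon-inducible genes differed, since the series concerns proteins of that group. They did: Rsad2 was at 51.7 ± 4.42 CPM in WT and 8.81 ± 2.54 CPM in KO cells, a log2 change of -2.45 (SE 0.221, adjusted p = 0.000106). Cmpk2, next to Rsad2 on chromosome 12, was lower by -1.93 (SE 0.131, adjusted p = 1.85e-05), Ifit1 by -1.86 (SE 0.132, adjusted p = 2.28e-05) and Ifit2 by -1.83 (SE 0.184, adjusted p = 0.000195). Of the 59 interferon-stimulated genes 45 were lower and 0 higher, or 49 and 0 adjusted over the list alone, with a median of -0.83 (camera adjusted p = 1.06e-29). That call was lost at an adjusted p = 0.185 with an estimated correlation. Of the 8 interferon-inducible GTPases 7 were lower and 0 higher, also adjusted over the list alone, with Gbp5 at -2.33 (SE 0.113) and a median of -1.32 (camera adjusted p = 4.96e-09, adjusted p = 0.0881 with an estimated correlation). Ifnb1 was at 29.7 ± 2.79 CPM in WT and 12.6 ± 2.62 CPM in KO cells, a log2 change of -1.19 (SE 0.136, adjusted p = 0.000418). Of the 17 followed genes 11 were lower, among them Irf7 (-1.18), Mx1 (-1.22) and Cxcl10 (-1.02), while Nos2, the inducible nitric oxide synthase, was higher by 0.88 (SE 0.189, adjusted p = 0.0125) and Cish by 0.72 (SE 0.118, adjusted p = 0.00297). Parp9 and Dtx3l, which lie next to Parp14 and overlap each other, were lower by -0.80 (SE 0.072) and -1.10 (SE 0.118). The strand setting of the counting is not given in the sources used here, so reads from their overlap are uncertain.

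Inflammatory genes of the other lists went both ways. Of those named here, Tap1 was also called lower with LPS and the inhibitor than with LPS alone, and Cxcl11 was lower without being called. Csf1, Ccl2 and Tnf were lower there too, with no overlap between the libraries. Csf1 stood at 34.1 and 35.71 CPM with LPS and at 26.34 and 20.18 CPM with LPS and the inhibitor. Ccl2 stood at 126.7 and 135.7 CPM with LPS and at 100.1 and 120.5 CPM with both. The monocyte chemokine Ccl2 (chromosome 11, 82035571 to 82037453, plus strand) was at 131 ± 6.36 CPM in WT and 15.9 ± 4.92 CPM in KO cells, a log2 change of -3.00 (SE 0.286, adjusted p = 0.00014). It was lower in KO cells before LPS too, at 4.741 and 6.747 CPM in untreated WT and 0.4763 and 1.229 CPM in untreated KO libraries. Mmp9 (chromosome 2, 164940780 to 164955850, plus strand) was at 6.82 ± 1.15 CPM in WT and 109 ± 3.66 CPM in KO cells, a log2 change of 3.83 (SE 0.216, adjusted p = 6.54e-06). Of the 30 cytokines and chemokines 6 were higher and 11 lower, or 8 and 12 adjusted over the list alone, and the list was not called (median -0.25, adjusted p = 0.0612; adjusted p = 0.0491 with the replicate block). The growth factor Csf1, Cxcl11 and Ccl7 were lower by -2.27, -2.12 and -2.02. Among the 35 NF-kB targets 4 were higher and 3 lower, also adjusted over the list alone (adjusted p = 0.792), with Ier3 at 1.19. Immediate early genes were 4 higher and 1 lower of 21, also adjusted over the list alone, with Dusp4 at 1.23 and Jun at 1.15 (adjusted p = 0.0984); with the replicate block they were 10 and 2 and the list was called upward (adjusted p = 0.0264), while without the block an estimated correlation gave an adjusted p = 0.624. Dusp4 and Jun stood higher in untreated KO libraries as well. Dusp4 was at 9.153 and 11.22 CPM in untreated WT and 22.16 and 29.88 CPM in untreated KO libraries, and Jun at 27.86 and 21.99 against 45.02 and 36.83 CPM. Tnf, Il1b, Il6 and Socs3 were not called, with log2 changes of -0.05 (SE 0.107), -0.11 (SE 0.23), 0.42 (SE 0.237) and -0.04 (SE 0.246). MHC class I presentation genes were lower in 6 of 18 cases and higher in 0, or 8 and 0 adjusted over the list alone, with the peptide transporter Tap1 at -0.96 (median -0.16, camera adjusted p = 0.000182, adjusted p = 0.077 with an estimated correlation).

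The sterol and stress lists differed after LPS as well. Of 24 sterol synthesis genes 21 were lower and 0 higher, or 22 and 1 adjusted over the list alone (median -0.47, camera adjusted p = 1.04e-16, adjusted p = 0.00146 with an estimated correlation), with Hmgcs1 at -0.81 and Hsd17b7 at -0.71. Of 20 unfolded protein and integrated stress response genes 13 were higher and 0 lower, or 15 and 1 adjusted over the list alone (median 0.51, camera adjusted p = 7.01e-11, adjusted p = 0.00745 with an estimated correlation), led by the glutathione-degrading enzyme Chac1 (1.82) and Trib3 (1.74). Slpi, Tbx3, Nid2, Hpgd and Dmwd were higher and Ndrg4, Gpnmb and Tmeff1 lower, as the largest changes besides those given. The MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 were again higher, by 2.59, 2.67 and 2.71. In all, 675 genes were higher and 835 lower, or 514 and 1082 under the deposited scaling, and 790 genes differed the same way with and without LPS (r = 0.797 across genes between the genotype differences). The count of 1510 was 3438 with the replicate block and 914 with the 4 libraries of the comparison alone. It was 868 to 921 without any of these 4 libraries.

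The share of counted alignments without a unique position also differed between the genotypes. It was 34.3% ± 0.745 in KO and 30.6% ± 1.59 in WT libraries of the untreated and LPS groups (SD, n = 4 each), a difference of 3.69 percentage points. The lowest KO value was 33.2% and the highest WT value 32.1% (two-sided exact permutation test over the 36 splits within treatments, p = 0.0556, the smallest p these splits allow).

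Next, the LPS responses of the genotypes were compared by their interaction, which asks whether LPS changed a gene differently in the KO cells. The number of KO clones is not given, so other differences between the lines cannot be told apart from the loss of Parp14 here. The interaction was negative for 31 genes, of which LPS raised 25 in WT cells, and positive for 14. Of the 31, Tbx3 had 0 reads in all WT groups, so its negative value is its fall in KO cells from 55.2 to 19.9 CPM. The GTPase Gbp5 (chromosome 3, 142493978 to 142522344, plus strand) went from 0.402 ± 0.103 to 10.6 ± 1.44 CPM in WT cells and from 0.166 ± 0.0494 to 1.31 ± 0.0384 CPM in KO cells, an interaction of -2.06 (SE 0.16, adjusted p = 0.000872). Among genes of at least 5 CPM, Csf1, Cxcl11, Rsad2, Ifit2 and the transcriptional repressor Prdm1 followed with -2, -1.90, -1.85, -1.73 and -1.67. Ifnb1 had an interaction of -1.19 (SE 0.193, adjusted p = 0.0376) and Ifit1 of -1.35 (SE 0.186, adjusted p = 0.0166). The largest positive value was that of the protease inhibitor Serpinb2 (chromosome 1, 107511423 to 107535478, plus strand), at 5.19 ± 0.0639 CPM in WT and 28.7 ± 0.779 CPM in KO cells after LPS (2.21, SE 0.122, adjusted p = 0.000114). The arginase gene Arg2, the cytokines Osm and Csf3, Bcar3 and Ier3 followed at this level with 1.38, 1.35, 1.32, 1.30 and 1.20. After LPS Bcar3 stood at 45.81 and 43.08 CPM in WT and 45.83 and 48.41 CPM in KO libraries. Untreated it stood at 34.61 and 39.71 CPM in WT and 14.21 and 16.63 CPM in KO libraries, so its interaction lies mainly in its level before LPS. By edgeR and DESeq2, which model ratios of reads without the added 1 CPM, the values turned to -0.09 and -0.11 for Csf3 and shrank to -0.18 and -0.09 for Prdm1, and neither test called these genes or Serpinb2. After LPS Prdm1 stood at 30.9 and 28.08 CPM in WT and 7.874 and 7.654 CPM in KO libraries, and Csf3 at 115.8 and 131 against 461.6 and 413.2 CPM. Untreated, Prdm1 was at 0.07606 and 0.1999 CPM in WT and 0.02507 and 0.05228 CPM in KO libraries, so its ratio rests on few reads. Csf3 was at 0.2028 and 0.1499 against 0.7521 and 0.5751 CPM there. Serpinb2 had 0 reads in untreated WT cells, so it has no defined ratio there, and its interaction rests on the added 1 CPM. Neither test called Gbp5 (-1.77 and -1.76), Cxcl11 (-1.82 by both), Ifnb1 (-1.27 and -1.28) or Arg2 (1.79 and 1.80), and edgeR also left Csf1, Rsad2, Ifit2, Ifit1 and Osm uncalled, all with the same sign. Tnf, Il1b and Il6 were not called, at -0.09 (SE 0.151), -0.31 (SE 0.326) and 0.44 (SE 0.336).

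Among interferon-stimulated genes, 7 of 59 had a negative interaction and 0 a positive one, or 28 and 0 adjusted over the list alone. The median interaction was -0.53 (camera adjusted p = 1.31e-40, adjusted p = 0.112 with an estimated correlation), and 42 members were called with the replicate block. Of the 8 GTPases 4 had a negative interaction, or 8 adjusted over the list alone, with 0 positive (median -1.07, camera adjusted p = 2.82e-20, adjusted p = 0.0479 with an estimated correlation). Cytokines and chemokines had 2 positive and 4 negative interactions of 30, or 3 and 8 adjusted over the list alone (median -0.20, camera adjusted p = 0.000314, adjusted p = 0.112 with an estimated correlation). The MHC class I list (median -0.12, camera adjusted p = 0.00426, adjusted p = 0.112 with an estimated correlation) and the sterol list (median -0.08, camera adjusted p = 0.00771, adjusted p = 0.112 with an estimated correlation) had 0 members called by limma. Adjusted over the list alone 1 and 0 were called, and with the replicate block 3 and 0. The block also called the immediate early list (camera adjusted p = 0.0393, against 0.202 without it) and the macrophage identity list (0.0393 against 0.0704). The 35 NF-kB targets had 1 stronger and 1 weaker response, also adjusted over the list alone (adjusted p = 0.549), in Ier3 (1.20) and Cd40 (-1.41). Cd40 differed before LPS, at 3.271 and 3.398 CPM in untreated WT and 9.827 and 8.783 CPM in untreated KO libraries. The count of 45 genes was 413 with the replicate block (182 positive and 231 negative), 19 with a pseudocount of 0.25, 76 without a filter, 10 by edgeR and 80 by DESeq2, with 674 genes at an unadjusted p under 0.05. It fell to between 17 and 22 without any single WT_UT, WT_LPS or KO_UT library or KO_LPS replicate 1, and was 31 without KO_LPS replicate 2.

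The inhibitor was given alone to WT cells as the control for its use with LPS. No gene was called: limma gave 0 genes at an adjusted p under 0.05, with 111 at an unadjusted p under 0.05 and a smallest adjusted p of 0.188, for Cxcl2. Without any change a share of about 0.05 of the 10899 tested genes would lie under 0.05, and 111 is a smaller share. With the replicate block 763 genes had an unadjusted p under 0.05. The fit without the block was therefore conservative here, and 0 calls do not show that the inhibitor had no effect. The edgeR test gave 0 genes, DESeq2 gave 2, and the replicate block 4, among them Cxcl2 (0.46, SE 0.058), the immediate early gene Fos (0.48, SE 0.0938) and Socs3 (0.61, SE 0.246). Adjusted over the list alone, 1 of 30 cytokines and chemokines and 1 of 21 immediate early genes were higher, and 1 of 16 LXR and lipid handling genes was lower. Parp14 was at 88.1 ± 16.5 CPM untreated and 88.5 ± 19.5 CPM with the inhibitor. None of the interferon-stimulated genes was called: 0 of 59 by limma, also adjusted over the list alone and with the replicate block. Camera called the list upward at a median of 0.03 (adjusted p = 0.0301, but adjusted p = 0.91 with an estimated correlation, 0.0781 after rescaling and 0.0764 with the block). Its median was -0.07 (adjusted p = 0.289) without WT_UT replicate 1 and -0.06 (adjusted p = 0.449) without WT_JAKi replicate 2, but 0.144 (adjusted p = 2.34e-10) without WT_UT replicate 2 and 0.13 (adjusted p = 1.08e-08) without WT_JAKi replicate 1. The unfolded protein and integrated stress response list was called upward as well (median 0.05, camera adjusted p = 0.0301, adjusted p = 0.605 with an estimated correlation, adjusted p = 0.0525 after rescaling), while the replicate block kept it (adjusted p = 0.0062); 0 members were called in any of these ways. Without WT_UT replicate 2 the count of genes was 1.

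In cells with LPS, the inhibitor was compared with LPS alone to find the part of the response that needs Jak kinases. Interferon-stimulated genes fell: Mx2 (chromosome 16, 97535308 to 97560900, plus strand) was at 68.3 ± 1.03 CPM with LPS and 5.61 ± 1.13 CPM with LPS and the inhibitor, a log2 change of -3.40 (SE 0.206, adjusted p = 4.4e-05). Rsad2 fell to 5.04 ± 0.323 CPM, a change of -3.12 (SE 0.221, adjusted p = 0.000104), followed by Cmpk2 (-2.87), Ifit2 (-2.81) and the GTPases Irgm2 (-2.72) and Irgm1 (-2.39). Of the 59 interferon-stimulated genes 46 were lower and 0 higher, or 55 and 0 adjusted over the list alone, with a median of -1.18 (camera adjusted p = 3.36e-124, adjusted p = 0.0102 with an estimated correlation). All 8 GTPases were lower, also adjusted over the list alone (median -1.45, camera adjusted p = 2.13e-32, adjusted p = 0.00689 with an estimated correlation). Of the 18 MHC class I genes Tap1 (-1.61, SE 0.109) and H2-T24 (-1.03, SE 0.184) were lower and 0 higher, with 3 lower adjusted over the list alone (median -0.13, camera adjusted p = 1.15e-08, adjusted p = 0.0102 with an estimated correlation). The interferon regulatory factor Irf7 was lower by -1.78 (SE 0.269), Parp9 by -0.85 (SE 0.072) and Dtx3l by -1.59 (SE 0.118).

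Few inflammatory genes were called with the inhibitor. Of 35 NF-kB targets and 30 cytokines and chemokines 0 were called by limma; adjusted over the list alone the counts were 0 and 2, and with the replicate block 0 and 4. The cytokine list was called downward (median -0.08, camera adjusted p = 0.0132, adjusted p = 0.274 with an estimated correlation), with Cxcl11 at -0.76 (SE 0.16, adjusted p = 0.0726) and Cxcl10 at -0.63 (SE 0.263, adjusted p = 0.651). Ifnb1 was at 29.7 ± 2.79 and 26.3 ± 2.98 CPM, a log2 change of -0.17 (SE 0.136, adjusted p = 0.933), and Tnf at 4517 ± 130 and 4181 ± 147 CPM. Sterol synthesis genes were higher with the inhibitor: 4 of 24 members, or 20 adjusted over the list alone and 18 with the replicate block, and 0 lower (median 0.28, camera adjusted p = 3.58e-22, adjusted p = 0.000648 with an estimated correlation). Hmgcs1 (chromosome 13, 119690379 to 119708260, plus strand) was at 183 ± 11.1 CPM with LPS and 283 ± 21.5 CPM with LPS and the inhibitor, a log2 change of 0.63 (SE 0.0822, adjusted p = 0.00434). Mvd and Fdft1, later enzymes of the pathway, and Insig1, which holds back sterol synthesis, rose by 0.52, 0.45 and 0.40. In all 8 genes were higher and 113 lower, 57 of these at least 2-fold; with the replicate block 183 were higher and 263 lower. The count of 121 was 55 without WT_LPS replicate 2 and 63 without WT_LPS_JAKi replicate 1. Of the 516 genes that LPS raised at least 2-fold in WT cells 46, or 8.91%, were lower with the inhibitor.

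**Figure D2:**
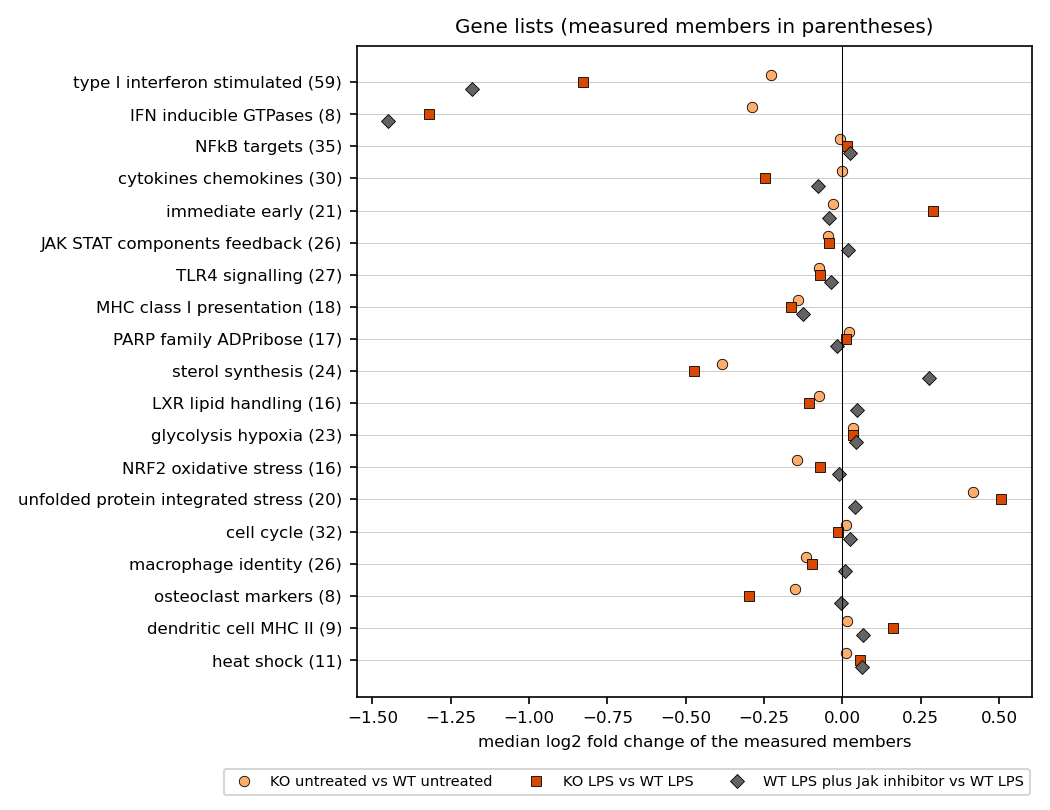
Median log2 change of the tested gene lists in KO vs WT untreated, KO vs WT after LPS, and LPS with the inhibitor vs LPS alone, with the number of measured members in parentheses; each point is the median of a list in a comparison. The type I interferon list stood at -0.23, -0.83 and -1.18, and the sterol synthesis list at -0.38, -0.47 and 0.28.

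Under the inhibitor, the LPS response was measured against cells with the inhibitor alone. Il1b rose by 9.27 (SE 0.23, adjusted p = 2.27e-09), Lif by 8.78 (SE 0.0897, adjusted p = 4.35e-12) and Cxcl2 by 8.21 (SE 0.058, adjusted p = 3.88e-13), and Kbtbd11 fell by 4.67 on the log2 scale. All 35 NF-kB targets were higher, also adjusted over the list alone (median 3.09, camera adjusted p = 3e-39), as were 29 of 30 cytokines and chemokines, also adjusted over the list alone (median 3.82, camera adjusted p = 3.37e-32). Of the 59 interferon-stimulated genes 7 were higher and 32 lower, the same adjusted over the list alone, and 11 and 25 after rescaling; the list was not called (median -0.43, adjusted p = 0.953). Isg15, Oasl1, Ifih1 and Ifit1 rose by 4.60, 3.57, 3.52 and 2.85 under the inhibitor. Rsad2 was not called (0.50, SE 0.221, adjusted p = 0.073), but was with rescaling (adjusted p = 0.0214) and the replicate block (adjusted p = 0.000448). Sterol synthesis genes were 15 higher and 4 lower of 24, or 15 and 5 adjusted over the list alone (median 0.37, camera adjusted p = 9.45e-07, adjusted p = 0.0109 with an estimated correlation). Other called lists were immediate early genes (camera adjusted p = 3.73e-09, adjusted p = 0.0957 with an estimated correlation), TLR4 signalling (0.0041 and 0.0565), cell cycle (3.32e-05 and 0.372), osteoclast markers (0.00618 and 0.372) and the dendritic cell and MHC class II list (0.000478 and 0.173). In all 1466 genes were higher and 5535 lower, of which 483 and 1152 at least 2-fold, and 2872 and 3541 after rescaling, which moved the median of all genes from -0.272 to -0.0334.

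The interaction of LPS and the inhibitor asked whether the inhibitor changed the LPS response itself. This interaction was negative for 62 genes and positive for 2, Hmgcs1 (0.70, SE 0.116, adjusted p = 0.0342) and Mvd (0.60, SE 0.0953, adjusted p = 0.026). The largest negative values were those of Mx2 (-3.37, SE 0.291, adjusted p = 0.00108), Rsad2 (-3.13, SE 0.313, adjusted p = 0.00173), Cmpk2 (-2.96), Ifit2 (-2.91), Irgm2 (-2.66) and Irgm1 (-2.48). Interferon-stimulated genes had a weaker response in 29 of 59 cases and a stronger one in 0, or 54 and 0 adjusted over the list alone and 55 and 0 with the replicate block (median -1.20, camera adjusted p = 1.52e-100, adjusted p = 0.0233 with an estimated correlation). Of the 8 GTPases 7 had a weaker response, or 8 adjusted over the list alone (median -1.48, camera adjusted p = 3.77e-27, adjusted p = 0.0111 with an estimated correlation). Tap1 of the MHC class I list (-1.53, SE 0.154) and Cxcl2 of the cytokine list (-0.64, SE 0.082) were the members called in these lists, with 2 and 1 weaker adjusted over the list alone. Cxcl2 stood at 5.644 and 6.25 CPM with the inhibitor alone and 3.955 and 4.148 CPM untreated, which makes part of its value. The MHC class I call (camera adjusted p = 0.000406) was lost at an adjusted p = 0.0669 with an estimated correlation, and the cytokine call (camera adjusted p = 0.0167) at an adjusted p = 0.353 with an estimated correlation. The immediate early list, with a median of 0.02, a mean of -0.11 and a downward test, was called at a camera adjusted p = 0.0368 but not at an adjusted p = 0.648 with an estimated correlation. The sterol list was called upward with 2 of 24 members stronger, or 9 adjusted over the list alone and 10 with the replicate block (median 0.28, camera adjusted p = 4.77e-17, adjusted p = 0.00142 with an estimated correlation). The count of 64 was 318 with the replicate block (133 positive and 185 negative), 118 by DESeq2 and 38 with the groups of the comparison alone. It was 30 to 39 without WT_UT replicate 1, either WT_LPS replicate, WT_JAKi replicate 2 or WT_LPS_JAKi replicate 1.

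The difference of KO from WT cells and the effect of the inhibitor were then set side by side in cells with LPS. Of the 113 genes lower with the inhibitor 94 were also lower in KO cells, where independent calls would share 8.66. Both comparisons use the same WT_LPS libraries, which alone makes them overlap. In 100 sets simulated with no true change and these libraries in common, the 835 and 113 genes with the lowest t shared 60 on average and 71 at most. Of the 113 genes 110 had a negative KO change, against 102 on average and 110 at most in the simulated sets, so this number carries the common libraries. Their median KO change was -0.76, against a mean of -0.154 and a lowest value of -0.196 in these sets. Across all 10899 genes the 2 changes had a Pearson r of 0.329 (Spearman rho 0.282), against a mean r of 0.501 in the simulated sets, so the r alone carries the common libraries. Their covariance was 0.02, against 0.00772 in the simulated sets. Sterol synthesis genes went in opposite directions, with medians of -0.47 in KO cells and 0.28 with the inhibitor. With the replicate block the overlap was 177, within the range of sets simulated with that block (166 on average, 189 at most). The simulated sets hold noise alone, while genes called lower in the data can carry large true changes, for which common noise weighs less. With or without the block, the sets therefore cannot say how much of the overlap the common libraries make.

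**Figure D3:**
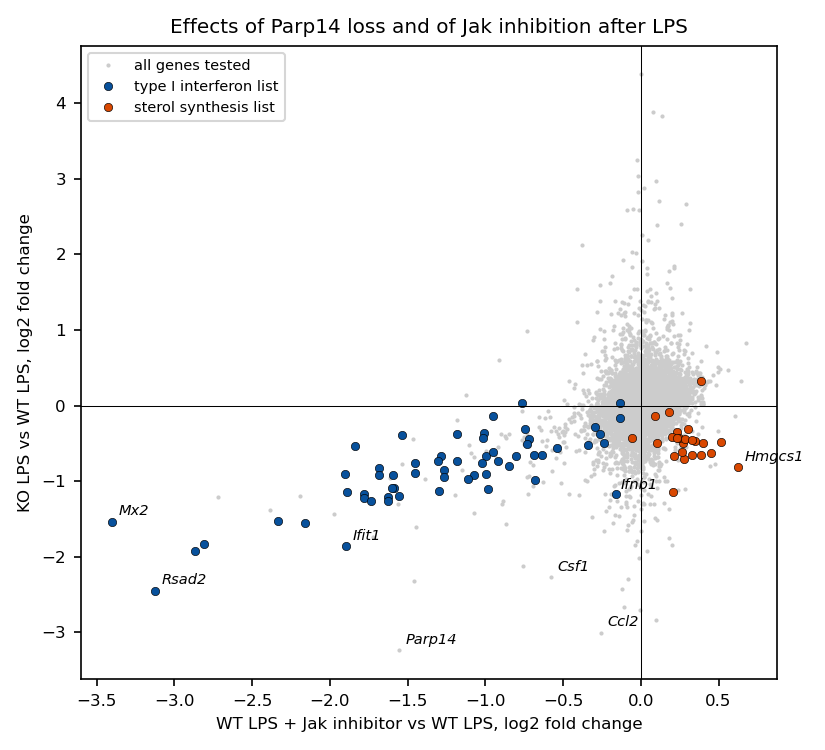
Log2 change of each tested gene with LPS and the inhibitor vs LPS alone (horizontal axis) and in KO vs WT cells after LPS (vertical axis). Grey points are all tested genes, blue points the type I interferon list (medians -1.18 and -0.83) and orange points the sterol synthesis list (medians 0.28 and -0.47).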

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

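The explanations tested with the values -0.068, -0.296 and -0.492 had their predictions written before those values were seen but after counts and the largest genes had been printed, and the test behind 31.7 was chosen after the result was seen.

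The LPS response differed between KO and WT cells, by a test of the difference itself, in 14 genes with a positive and 31 with a negative interaction. Positive were Serpinb2 (2.21), Arg2 (1.38), Osm (1.35), Csf3 (1.32), Bcar3 (1.3) and Ier3 (1.2). Of these Csf3 turned sign in the count-based tests, and Bcar3 differed between the genotypes mainly before LPS. Serpinb2 had 0 reads in untreated WT cells, so that its ratio there is undefined. Negative were Gbp5 (-2.06), Csf1 (-2), Cxcl11 (-1.9), Rsad2 (-1.85), Ifit2 (-1.73) and Prdm1 (-1.67), which shrank to -0.18 by edgeR and -0.093 by DESeq2; neither of these tests called Serpinb2, Arg2, Csf3, Gbp5, Cxcl11 or Prdm1. Csf3 and Prdm1 were under 1 CPM in untreated KO and WT libraries, where ratios are uncertain. After LPS Csf3 was higher and Prdm1 lower in KO than in WT libraries. The type I interferon list had a median difference of -0.534 between the responses, not called with an estimated correlation (adjusted p = 0.112). The share of counted alignments without a unique position, which enters the deposited scaling but not the scaling over gene reads, was 3.69 percentage points higher in KO than in WT libraries.

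Interferon-stimulated genes were lower in KO than in WT cells after LPS, 45 of 59 members by single tests, while the call of the list was lost with an estimated correlation (adjusted p = 0.185). A weaker response of the KO cells as a whole would lower NF-kB targets too, but the 33 of these raised at least 2-fold in WT cells had a median interaction of -0.068 (SE 0.0795). A difference already there without LPS would show in untreated cells at a similar size, but the 45 lower members had a median of -0.296 (SE 0.0386) untreated against -0.925 after LPS. These 45 were chosen for being lower after LPS, which enlarges the value there. Over all 59 members the median was -0.229 untreated and -0.829 after LPS. The untreated median of the list was -0.362 without WT_UT replicate 1 and -0.159 without WT_UT replicate 2. Both SE are over genes and leave out the spread between libraries. Both explanations were argued against as the whole cause, by these medians and not by a test over libraries. Ifnb1 was lower in KO cells too, and a smaller amount of interferon beta could contribute to the lower genes, which these libraries do not test.

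Untreated KO and WT cells differed in 1055 genes. RNA of dendritic cells in the KO libraries, a possible reading of the higher MHC class II genes, would raise other dendritic markers. Zbtb46, Itgax, Cd83 and Xcr1 had a median difference of -0.492 (SE 0.321), below the bound set beforehand, and none of these had both KO libraries above the WT libraries. That bound had no basis, since how much a small share of such RNA would add to these markers is not known here. Zbtb46, Itgax and Xcr1 were under 5 CPM in WT cells. Cd83 was at 54.9 CPM in WT cells, where a small share would not show. The cells were of a macrophage line and no dendritic cells were part of the design, but the markers alone left the explanation open. The labels do not say how many KO clones were made, so divergence of the KO cells for reasons other than Parp14 could account for any of these genes and was not tested by the design. The same holds for the genotype differences after LPS and in the response to LPS.

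More genes were called lower than higher after LPS in WT cells by limma, 5839 against 1493, but 3537 against 2873 after rescaling by the median of ratios, 3422 against 3052 by edgeR and 3225 against 3318 by DESeq2. If genes raised by LPS take up reads, the other genes lose share without a change in their own amount. The 516 genes raised at least 2-fold took 12.4% of gene reads after LPS against 2.39% untreated, which lowers the others by 0.156 on the log2 scale, while the median of all genes shifted by -0.302. With library sizes over the other genes 31.7% of the called genes were higher, against 20.4% before. So the split depended on the scaling and the raised genes accounted for part of it, and for the rest a further effect of scaling and a loss of RNA in many genes at once cannot be told apart.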

How the results depend on the processing

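Of 134 alternatives for the counts of called genes 91 stayed within 1.5 times, and of 89 for the type I interferon list 79 kept direction and call. The deposited scaling left 189 of 191 reported gene changes the same, rescaling by the median of ratios 188, the pseudocount of 0.25 182, DESeq2 179, edgeR 176 and a limit of 2-fold 169. Under the deposited scaling the share of higher genes between KO and WT cells was 24% untreated and 32.2% after LPS. Where a result changed, the cause was not tested, except that a limit of 2-fold lowers counts by construction. A group with a library left out had 1 library and was assumed to vary like the others.

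A limit of 2-fold left 1733 genes in WT and 1760 in KO cells after LPS, 173 between untreated KO and WT cells, 214 between KO and WT cells after LPS, 57 for the inhibitor with LPS, 1635 for LPS under the inhibitor and 28 in the overlap of genes lower in KO cells and with the inhibitor. With only the groups compared, 914 genes were called between KO and WT cells after LPS and 38 for the interaction of LPS and the inhibitor. For the genotype by LPS interaction the count was 19 with a pseudocount of 0.25, 76 with no filter, 10 with edgeR and 80 with DESeq2. DESeq2 gave 118 for the interaction of LPS and the inhibitor and 2 for the inhibitor alone, where limma gave 0 (111 at an unadjusted p under 0.05) and edgeR 0.

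With the replicate number as a block, 2685 genes were called between untreated KO and WT cells, 3438 after LPS, 413 for the genotype by LPS interaction, 4 for the inhibitor alone, 446 for the inhibitor with LPS, 318 for the interaction of LPS and the inhibitor and 177 in the overlap. Besides those given beside the results, the block raised no count of a comparison by over 1.5 times. For the inhibitor alone the interferon list had a median of 0.031 with the block (adjusted p = 0.0764).

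With an estimated correlation the interferon list was not called for WT LPS (0.858, adjusted p = 0.179), KO LPS (0.326, adjusted p = 0.402), untreated KO and WT cells (-0.229, adjusted p = 0.826), KO and WT cells after LPS (-0.829, adjusted p = 0.185), the genotype by LPS interaction (-0.534, adjusted p = 0.112) and the inhibitor alone (0.031, adjusted p = 0.91). For the inhibitor alone it was 0.036 after rescaling by the median of ratios (adjusted p = 0.0781), -0.069 and 0.144 without WT_UT replicate 1 and 2 (adjusted p = 0.289 and 2.34e-10), and 0.13 and -0.059 without WT_JAKi replicate 1 and 2 (adjusted p = 1.08e-08 and 0.449).

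Leaving out libraries moved the count between untreated KO and WT cells to 477 (WT_UT replicate 1), 548 (WT_UT replicate 2), 510 (KO_UT replicate 1) and 502 (KO_UT replicate 2). After LPS it was 901 (WT_LPS replicate 1), 868 (WT_LPS replicate 2), 886 (KO_LPS replicate 1) and 921 (KO_LPS replicate 2). The genotype by LPS interaction had 21 and 22 genes without WT_UT replicate 1 and 2, 20 and 19 without WT_LPS replicate 1 and 2, 17 and 19 without KO_UT replicate 1 and 2, and 21 without KO_LPS replicate 1. The inhibitor alone had 1 without WT_UT replicate 2. The inhibitor with LPS had 55 without WT_LPS replicate 2 and 63 and 96 without WT_LPS_JAKi replicate 1 and 2. The interaction of LPS and the inhibitor had 30 without WT_UT replicate 1, 38 and 31 without WT_LPS replicate 1 and 2, 35 without WT_JAKi replicate 2 and 39 and 54 without WT_LPS_JAKi replicate 1 and 2. The correlation of the LPS responses was 0.9747 with a filter of 5 CPM, 0.9639 without WT_UT replicate 1, 0.9621 without WT_LPS replicate 2, 0.9667 and 0.9617 without KO_UT replicate 1 and 2, 0.963 without KO_LPS replicate 1 and 0.9632 without KO_LPS replicate 2.

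Gene changes that turned sign were small and not called before or after, save for Serpinb2, Csf3 and Ccl7. Serpinb2 had 0 reads in untreated WT and Ccl7 in untreated KO cells, so their ratios are undefined there and the sign in the count-based tests carries no information. For the genotype by LPS interaction edgeR and DESeq2 gave Serpinb2 -1.139 and -0.604 and Csf3 -0.087 and -0.109, and Tnf was 0.049 and -0.227 without WT_UT replicate 1 and 2. Ccl7 was 0.437 with edgeR in the comparison of the KO with the Jak-inhibited response. Between KO and WT cells after LPS, Il1b was 0.014 and -0.242 without WT_LPS replicate 1 and 2, and Socs3 was 0.03 without WT_LPS replicate 1 and -0.21 and 0.134 without KO_LPS replicate 1 and 2. Parp14 with the inhibitor alone was -0.003 with the deposited scaling, -0.187 without WT_UT replicate 1, and 0.227 and -0.221 without WT_JAKi replicate 1 and 2. The level of Parp14 with the deposited scaling was 48.91 and 62.66 in untreated WT libraries 1 and 2, 193.6 and 258.1 with LPS, 47.78 and 63.86 with the inhibitor, 70.33 and 85.83 with both, 5.987 and 7.109 in untreated KO libraries and 20.6 and 23.96 in KO libraries with LPS, as the summary lines then count in the library size. After rescaling by the median of ratios it was 45.13 in KO_LPS replicate 2.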

Other observations

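The comparison of the KO response with the Jak-inhibited response to LPS was added after the other results were seen, as was the test of 25 genes behind the value 6. In WT cells under the inhibitor, LPS left more interferon-stimulated genes without a rise than in KO cells. Of 59 members 6 responded more in KO cells than in WT cells under the inhibitor and 0 less by limma, or 39 and 0 adjusted over the list alone (median 0.70, camera adjusted p = 3.15e-41, adjusted p = 0.254 with an estimated correlation), with Mx2 at 2.32 (SE 0.291, adjusted p = 0.0123) and Irgm1 at 1.56. Sterol synthesis genes responded less in KO cells, with 3 of 24 called and 21 adjusted over the list alone (median -0.39, camera adjusted p = 1.13e-22, adjusted p = 0.000592 with an estimated correlation). Called upward but lost with an estimated correlation were the interferon-inducible GTPases (camera adjusted p = 0.0048, then adjusted p = 0.515) and immediate early genes (camera adjusted p = 0.000229, then adjusted p = 0.515). Cytokine genes Csf1 (-1.37) and Ccl7 (-1.94) and the receptor Cd40 (-1.44) also responded less in KO cells by limma. Neither count-based test called Csf1 (-1.07 and -1.06) or Ccl7, which had 0 reads in untreated KO cells and so no defined ratio there. Cd40 was at 9.31 CPM in untreated KO cells and 3.01 CPM in WT cells with the inhibitor, but at 110 and 115.5 CPM after LPS, so its smaller response lies in its level before LPS. In all 60 genes were called by limma, 29 with more and 31 with less response in KO cells. The count was 590 with the replicate block, 136 with DESeq2, 35 with a pseudocount of 0.25, 30 with a filter of 5 CPM or a limit of 2-fold, 27 with edgeR and 12 with only the groups compared. It was 9 without KO_UT replicate 1 and between that and 31 without any other library.

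Of the 31 genes with a negative genotype by LPS interaction 13 also had a negative interaction of LPS and the inhibitor. Both use the same untreated and LPS libraries of WT cells, and in 100 sets simulated with no true change the genes with the lowest t shared 6.84 on average and 12 at most. With the replicate block 99 were negative in both, against 45.9 on average and 58 at most in sets simulated with that block. These sets hold noise alone too, so they cannot say how much of the overlap the common libraries make. If loss of the Jak-dependent part of the response were the only cause, the 25 of these genes that LPS raised in WT cells would respond no less in KO cells than in WT cells under the inhibitor. Of the 25 genes 6 responded less in KO cells and 3 more by limma, but edgeR called 1 less, Cd40, and 3 more, and DESeq2 3 less and 6 more. With the replicate block 12 responded less and 7 more, and after rescaling by the median of ratios 8 and 3. The 25 genes were chosen by a comparison that uses the same KO libraries, which alone favours a smaller response in KO cells here. So whether loss of the Jak-dependent part was the only cause was left open.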
